A study of Homo sapiens with 6 samples.

How the data were processed

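ATAC-seq libraries of 6 T-ALL cell lines, 1 library per line, were analysed from the peak lists that the authors deposited. Per the labels, cells grown in RPMI medium were incubated with Tn5 and the libraries were read as paired ends on an Illumina NovaSeq. The submitters' processing notes name Bowtie2, Picard, SAMtools and MACS2 2.1.1.2016030 and the genome build hg19; their order and settings are not given in the sources used here, nor is any shift of reads for the Tn5 cut. Peaks were called per library, as the files show, with 1 list for each line.

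The lists have no header line and were read as narrowPeak. For each summit the authors give a score, a fold enrichment over the local background, and the −log10 of a p-value and of a q-value. The score in the authors' lists equals 10 times the −log10 p, rounded down, in all but 7 of 139886 lines. The lowest −log10 p in each of the deposited lists lies just above 5. Lines that share an interval were joined, and the strongest summit was kept for its values. Lines outside chromosomes 1 to 22 and X, mitochondrial ones included, were left out of the comparisons.

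Intervals on chromosomes 1 to 22 and X that overlapped by at least 1 bp were merged across lines, and a line was counted in each region that held a peak of it. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Jaccard indices were set beside 100 shuffles of peaks within chromosomes. Runs of missed regions were set beside 1000 permutations that kept the number of other lines with a peak. With 1 library per line no test between lines against replicate error was possible, and no p-value is given for a difference between lines. Dixon's gap ratio over the 6 lines served to point out values, and chances from permuted or matched regions describe 1 library. Named peaks follow a rule: for each line the 4 line-only peaks with the highest −log10 p, of which the first 1 or 2 are printed here, and the 2 regions missed by that line alone that ranked highest in the others, of which some are printed, and the 3 longest runs.

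These comparisons, their alternatives and the naming rule were set before the data were examined. The following was added after seeing the data: the recovery of pileups, the relative tag depth, the relative pileups per chromosome and part of a chromosome, the exclusive pairs and sets of 3 lines, the split by region density, the ratios of TALL-1 to single lines on chromosome 21, and the search for steps along chromosomes. A first test of chromosome 21 compared only its lower 44 and upper 45 regions; it was replaced by 8 parts after the profile was seen. A first test of strong regions on chromosome 21, which had left them open, was likewise replaced. Call rates at 200 matched regions for each region of the stretch on chromosome 2 were also added. One threshold in the scaling of line-only regions was also corrected after first values were seen, and both versions are reported.

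Pileups were recovered from the authors' fold and −log10 p as the whole number of tags t and background c for which the fold is (t + 1) / (c + 1) and the p-value is the Poisson chance of more than t tags. A match within 0.001 of the −log10 p was found for 99.8% to 99.9% of lines per library; values of 250 and above were not tried. The relative tag depth is the lowest background divided by the smallest interval width, scaled to CCRF-CEM, and it assumes that this width is the caller's extension length. Mitochondrial peaks appear in every list, so this depth may include mitochondrial tags. Relative pileups are log2 values at 9042 shared regions, taken against the mean of the 6 lines and centred on each line's median, with 1000 bootstrap draws over regions. Region density is the number of shared regions within 500 kb on each side.

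The recovery of pileups, the merging, the run search, the chromosome pileups and the search for steps were tested on simulated data. For the search for steps this was done only after it had first been run on the real lists. The shuffles, the scaling of line-only regions, the density trend, the exclusive pairs, the gap ratios and the matched call rates were not tested in this way. Of the simulated summits 100.0% gave the right pileup. The merging found 100.0% of the simulated shared regions among 40110, and a planted run of 14 regions was found as 15, a missed neighbour having joined it. A doubled chromosome, set at 0.83 against the mean of 6 lines, was found at 0.80. The search for steps placed 99 of 100 planted steps within 2 regions, and 4 of 100 simulated chromosomes without a step passed the 5% level. The values simulated for it were independent between neighbouring regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.

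No annotation or genome of build hg19 was used here, and coordinates were not converted. Positions are given 1-based in hg19 without the genes or sequence features they lie in. The planned promoter shares, the 16 gene lists, the windows around transcription factor genes and the motif counts were therefore not run.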

Results

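Open chromatin was mapped by ATAC-seq in 6 established cell lines of T-cell acute lymphoblastic leukaemia (T-ALL), a cancer of immature T cells. The lines were CCRF-CEM, DND-41, HBP-ALL, KOPT-K1, MOLT-4 and TALL-1. ATAC-seq uses the Tn5 transposase to cut and tag accessible DNA, so that positions with many tags mark open chromatin. Each line was represented by 1 library, and no replicate error exists for any value given here. The values describe these libraries, and a difference between lines cannot be separated from a difference between preparations. The series addressed which regions were accessible in T-ALL lines; its labels name no treatment or control.

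The authors' peak lists held between 16507 intervals in TALL-1 and 22367 in CCRF-CEM on chromosomes 1 to 22 and X. DND-41 had 17898 intervals, HBP-ALL 22055, KOPT-K1 18114 and MOLT-4 19114. Peaks covered from 9.33 Mb of the genome in TALL-1 to 12.1 Mb in HBP-ALL. CCRF-CEM peaks were the narrowest, with a median width of 436 bp against 491 to 531 bp in the other 5 lines. Only 9.18% of CCRF-CEM intervals held several summits, against 15.0% to 19.9% elsewhere. The read totals behind the lists are not known here. The lowest background recovered from each list gave a relative tag depth, with CCRF-CEM set to 1, of 1.35 for MOLT-4, 1.55 for KOPT-K1, 1.70 for DND-41, 1.93 for HBP-ALL and 2.096 for TALL-1. The library with the fewest tags on this scale thus had the most intervals, and the library with the most tags had the fewest.

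The 6 peak sets merged into 40110 regions, of which 9053 (22.6%) held a peak in every line. Another 17315 regions (43.2%) held a peak in 1 line only. Regions with peaks in 2, 3, 4 and 5 lines numbered 5436, 3218, 2468 and 2620. Shared regions were wide, with a median of 880 bp, but joining the intervals of several lines widens a merged region by construction. Regions of a single line were narrow, with a median of 304 bp. They were also weaker: in CCRF-CEM the median pileup, the number of tags stacked at the summit, was 13 at its line-only regions and 31 at the regions shared by all lines. In TALL-1 the corresponding medians were 14 and 44.

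**Figure D1:**
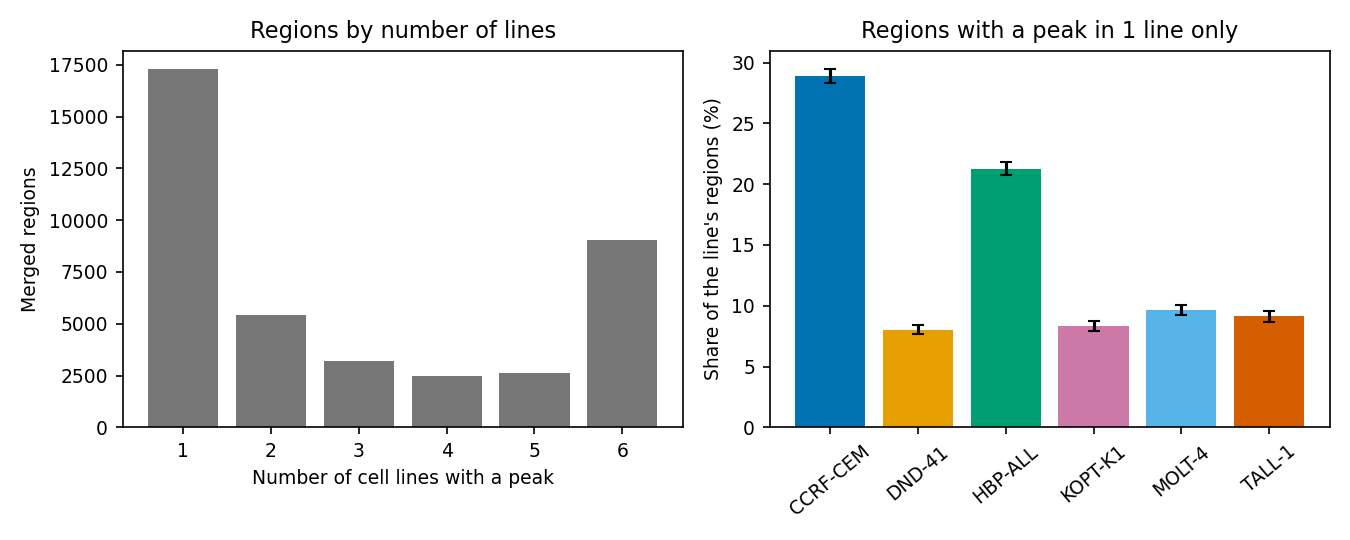
Left, number of merged regions (y axis) by the number of cell lines with a peak (x axis). Right, the share of each line's regions, in percent, that held a peak of that line only, with exact binomial 95% intervals that cover counting error only; CCRF-CEM stands at 28.9% and HBP-ALL at 21.3%, above 8.04% to 9.62% in the other 4 lines. All peaks are used; with equal numbers per line HBP-ALL had 2465 such regions and TALL-1 2060.

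CCRF-CEM had 6420 line-only regions, 28.9% of its regions (exact binomial 95% interval 28.3% to 29.5%). HBP-ALL followed with 4654, or 21.3% (20.7% to 21.8%). The other lines had 1825 in MOLT-4 (9.62%), 1498 in KOPT-K1 (8.34%), 1490 in TALL-1 (9.12%) and 1428 in DND-41 (8.04%). These intervals cover counting error only and hold no spread between libraries. With equal numbers of the strongest peaks in every line the counts were 3793 in CCRF-CEM, 2465 in HBP-ALL and 2060 in TALL-1, and 1399 to 1439 in the other 3 lines, so that HBP-ALL stood less far from the rest. CCRF-CEM line-only regions lay mostly where shared regions were sparse: among 3 classes of merged regions by density, 3501 fell in the sparsest and 1106 in the densest. In that densest class HBP-ALL had more, at 1243. Scaled to the other libraries, 57.7% to 83.9% of the CCRF-CEM line-only regions would have reached the threshold in all 5 of them, depending on the scaling and threshold. The 57.7% took a threshold raised by 1 tag. Such shares are biased upward, because line-only regions are picked for being high in that line. For the line-only regions of the other lines they ran from 53.8% in DND-41 to 93.6% in HBP-ALL.

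The strongest line-only peak of CCRF-CEM lay on chromosome 1 at 194504214 to 194504859, with a −log10 p of 126.5 and a pileup of 138 over a local background of 6.76. Its next strongest lay on chromosome 3 at 19853086 to 19853669, with a −log10 p of 103.7. In DND-41 the strongest was on chromosome 5 at 96528446 to 96529238 (−log10 p 63.1, pileup 82), followed by chromosome 7 at 26903868 to 26904737 (−log10 p 55.9). HBP-ALL led with chromosome 5 at 15271645 to 15272200 (−log10 p 54.6, pileup 60). In KOPT-K1 the leading peak was on chromosome 12 at 127256625 to 127257224 (−log10 p 56.6, pileup 69). MOLT-4 had its strongest on chromosome 7 at 151722483 to 151723159 (−log10 p 55.1, pileup 66), and 2 of its 4 strongest lay on chromosome 4. The strongest TALL-1 line-only peak, on chromosome 4 at 52986 to 53398, stood on a local background of 56.6 and 565 bp from a peak of another line. The next in TALL-1, on chromosome 6 at 10404178 to 10404875, had a pileup of 67 over a background of 5.25. The −log10 p values are the authors' own, and the pileups and local backgrounds were recovered from the authors' values; none is compared between lists.

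CCRF-CEM lacked a peak at 971 regions that all 5 other lines shared, and TALL-1 at 630. The other lines lacked 296 (HBP-ALL), 277 (KOPT-K1), 225 (MOLT-4) and 221 (DND-41). A missing peak means that no call reached the authors' threshold; it is not a measurement of closed chromatin. TALL-1 had no peak on chromosome 3 at 190231263 to 190232811, where the other lines had pileups of 91 to 277, and its nearest peak lay 1188320 bp away. It also had none on chromosome 5 at 108084080 to 108085118, where pileups elsewhere were 89 to 179. DND-41 lacked a peak on chromosome 13 at 103046421 to 103047286 (59 to 124 in the others) and on chromosome 2 at 167231924 to 167232939 (64 to 185). HBP-ALL lacked one on chromosome 9 at 82186144 to 82187048 (83 to 193), and MOLT-4 on chromosome 12 at 31881619 to 31882470 (63 to 96). For CCRF-CEM the strongest such region was a narrow one on chromosome 11, at 85195011 to 85195228, with pileups of 112 to 181 in 4 other lines; that of MOLT-4 was not recovered. For KOPT-K1 it was on chromosome 7 at 61970263 to 61970522, only 502 bp from a KOPT-K1 peak. Pileups there were 414 to 759 in 4 other lines, and that of TALL-1 was not recovered. This region lies close to the largest gap without regions on chromosome 7, which ends at 61968697. No list of artefact-prone regions was used here to filter the peaks.

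DND-41 and KOPT-K1 had the most similar peak sets, with a Jaccard index of 0.557, the bases covered in both lists divided by those covered in either. CCRF-CEM and HBP-ALL had the least similar, at 0.394. Shuffling the peaks within chromosomes gave mean indices near 0.002 for every pair, with 0.00249 as the highest of 100 shuffles over the 15 pairs. By this index CCRF-CEM was the line farthest from the rest, with a mean of 0.418 with the other 5, followed by HBP-ALL at 0.470. The remaining lines had means of 0.494 (TALL-1), 0.503 (MOLT-4), 0.506 (KOPT-K1) and 0.511 (DND-41). With equal numbers of the strongest peaks in every line, the least similar pair became CCRF-CEM and TALL-1.

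DND-41 and KOPT-K1 also ranked peak heights most alike. Over 9042 shared regions their recovered pileups had a Spearman correlation of 0.806, and CCRF-CEM and TALL-1 had the lowest, at 0.514. The mean correlation with the other 5 lines was nearly the same in CCRF-CEM (0.647) and TALL-1 (0.649), the lowest values. MOLT-4 (0.678) came next and HBP-ALL stood at 0.695, so this order differs from that of the Jaccard index. These are correlations across regions, which are not independent replicates. The pair DND-41 and KOPT-K1 shared 406 regions with no other line, 1.53 times the number set by each line's total of such regions. DND-41 and HBP-ALL shared 258, or 0.633 times that number. Among sets of 3 lines, HBP-ALL, KOPT-K1 and MOLT-4 shared the most regions exclusively, 326, and CCRF-CEM, KOPT-K1 and TALL-1 the fewest, 69.

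**Figure D2:**
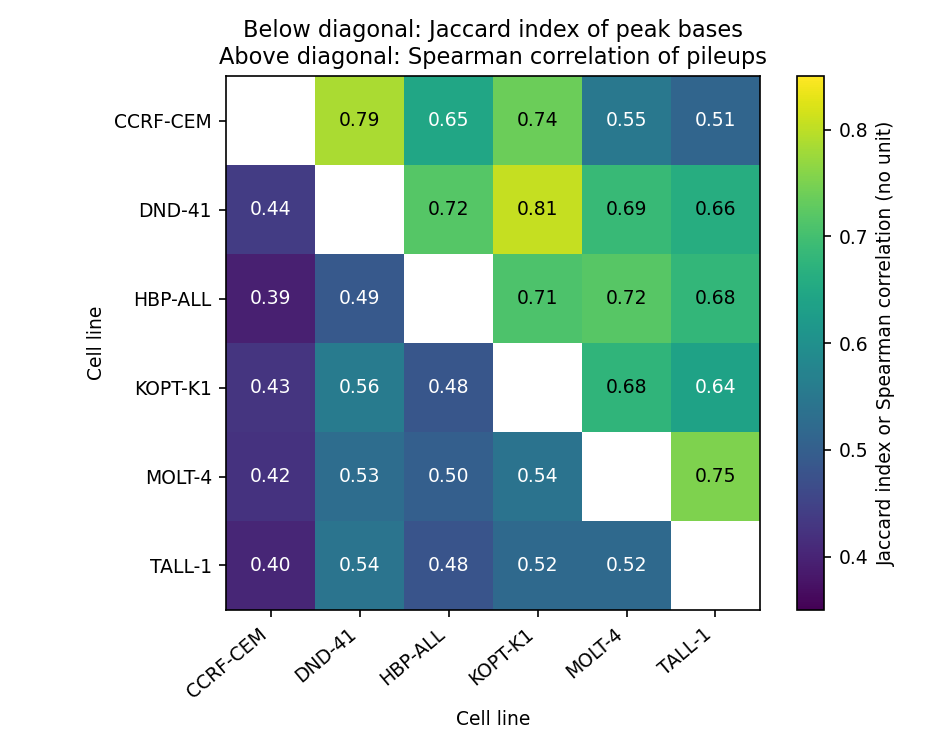
Similarity of the 6 cell lines, 1 library each: below the diagonal the Jaccard index of bases covered by peaks, above it the Spearman correlation of recovered pileups over 9042 shared regions (both without unit). DND-41 and KOPT-K1 have the highest value of each kind, 0.557 and 0.806.

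In TALL-1, 13 consecutive recurrent regions, those with peaks in at least 3 of the other 5 lines, held no peak. They spanned 4.60 Mb on chromosome 2, from 153587104 to 158184466. The stretch held 57 merged regions in all, with 34 peak regions in CCRF-CEM, 29 in DND-41, 15 in HBP-ALL, 15 in KOPT-K1, 13 in MOLT-4 and 0 in TALL-1. TALL-1 peaks resumed at 158260972. When the missed regions of TALL-1 were permuted among recurrent regions, 0 of 1000 draws gave a run of 13, and the longest permuted run was 12. The permutation treats neighbouring regions as independent and keeps neither chromosome nor region density. When recurrent meant peaks in at least 4 of the other lines, the TALL-1 run on chromosome 2 shortened to 6 and no longer passed. With equal numbers of the strongest peaks in every line 7 runs passed. The longest of these were 17 and 13 regions in CCRF-CEM on chromosome 19, and the TALL-1 run on chromosome 2 had 11.

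The next runs did not exceed the permuted 95th percentile. CCRF-CEM lacked 9 recurrent regions in a row on chromosome 7 from 142154149 to 142273972, and 64 of 1000 draws gave a run as long. TALL-1 lacked 9 on chromosome 7 from 113350311 to 116152516, with 65 of 1000 draws as long.

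**Figure D3:**
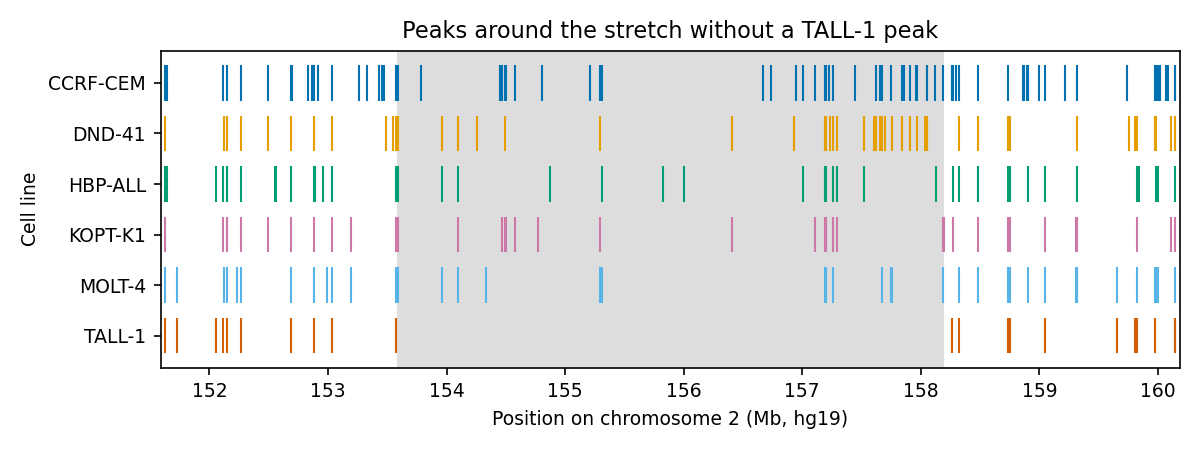
Peaks of each cell line (rows, 1 tick per peak) by position on chromosome 2 in Mb (x axis, hg19). The grey band is the stretch from 153587104 to 158184466, where TALL-1 has 0 peaks and the other lines have 13 to 34 peak regions.

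CCRF-CEM had few peaks on chromosomes 17 and 19, which held 2.56% and 2.52% of its intervals. The other lines had 4.10% to 5.02% of their intervals on chromosome 17 and 4.04% to 5.46% on chromosome 19. TALL-1 had 1.73% of its intervals on chromosome 21, and the other lines 0.745% to 1.26%. MOLT-4 had 1.24% on chromosome 18, against 1.79% to 2.20% elsewhere. On chromosome 2 the share was 9.38% in CCRF-CEM and 6.55% in TALL-1.

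Peak heights at shared regions differed along the same chromosomes. Relative pileup is given as log2 against the mean of the 6 lines, centred on each line's median. TALL-1 stood at 1.06 on chromosome 21 (bootstrap 95% interval 0.92 to 1.19 over 89 regions) and at 0.55 on chromosome 20. KOPT-K1 was at −0.69 on chromosome 21 (−0.78 to −0.63), and MOLT-4 at −0.60 on chromosome 18 (−0.67 to −0.53). CCRF-CEM was at −0.43 on chromosome 16, −0.25 on chromosome 20, −0.37 on chromosome 21 and −0.34 on chromosome 22. It was lower on chromosomes 17 and 19, at −0.64 and −0.68, and at −0.52 and −0.45 with the trend in region density removed. That removal left MOLT-4 at −0.50 on chromosome 18 and TALL-1 at 1.08 on chromosome 21. HBP-ALL stood at −0.66 on chromosome 3 below the gap that ends at 93560487 and at 0.02 above it. The bootstrap intervals cover the spread between regions, not between libraries. Because each value is relative to the mean of the 6 lines, a high value in 1 line lowers the others.

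**Figure D4:**
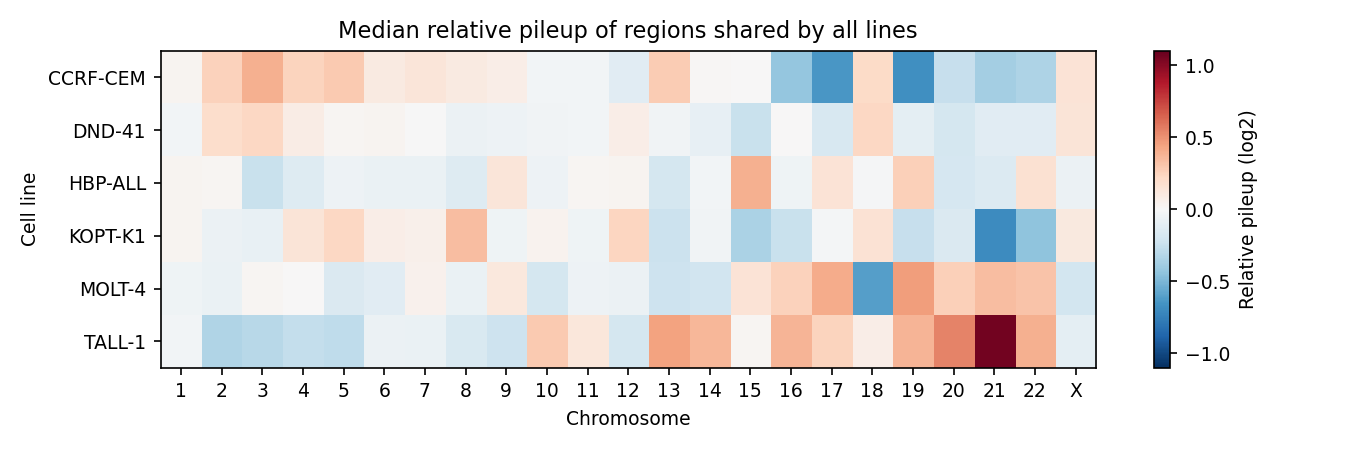
Median relative pileup (log2, colour) of regions shared by all lines, by chromosome (x axis) and cell line (rows, 1 library each). The highest value is TALL-1 on chromosome 21 at 1.06 and the lowest KOPT-K1 on chromosome 21 at −0.69.

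The high TALL-1 values on chromosome 21 did not extend along its whole length. Among 8 parts with nearly equal numbers of regions, the first 6, from 9695893 to 40752697, had medians from 0.73 to 1.36. The last 2, up to 48055995, had medians of −0.29 and −0.28. These medians hide lower regions within the high parts. Neighbouring regions from 23793370 to 25341826, across the border of the first and second part, stood at −0.06, −0.19 and −0.34. Another, at 40177095 to 40178352, stood at −0.68. A search for a single split cannot show such inner drops. With the density trend removed, the best single split of the chromosome lay between 43299891 and 43429640, inside the part before the last. The TALL-1 step there was −1.40, and its medians before the trend was removed were 1.21 over the 70 regions below and −0.30 over the 19 above. MOLT-4 stood at 1.03 and 1.01 in these last 2 parts and HBP-ALL at 0.26 and 0.50, which lowers the TALL-1 values relative to the mean. Against each other line singly, the log2 ratio of TALL-1, centred on its median over all shared regions, was 1.01 to 1.83 over the first 6 parts. In the last part it was −1.24 against MOLT-4, −0.60 against HBP-ALL, −0.47 against DND-41, 0.20 against CCRF-CEM and 0.76 against KOPT-K1. The bootstrap interval of the last part was −0.57 to −0.02. That of the part before it, 40817239 to 45209789, was wide at −0.44 to 1.43, because high and low regions met within it.

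**Figure D5:**
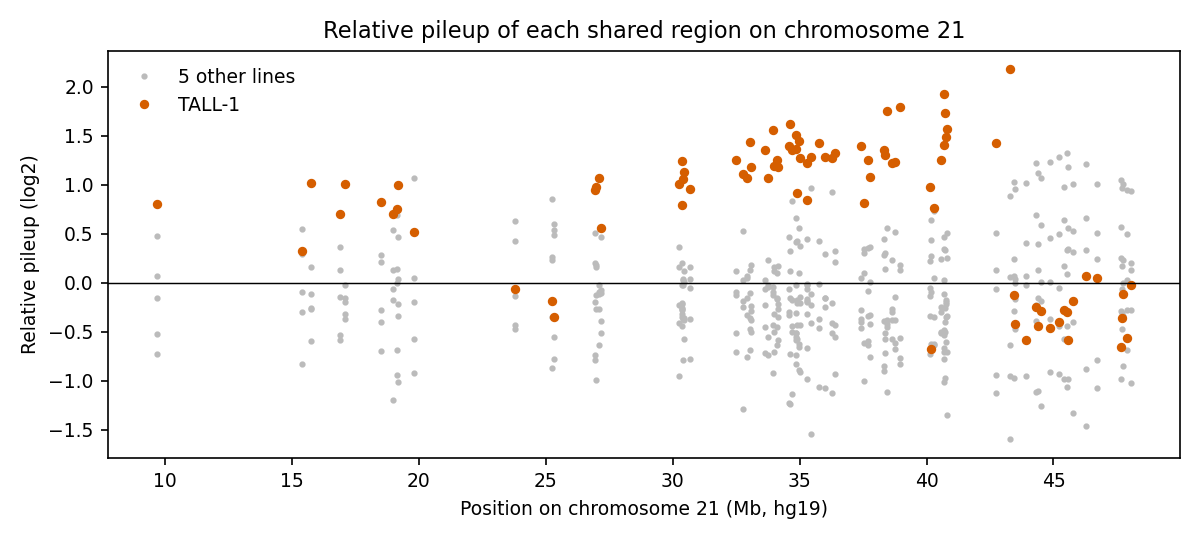
Relative pileup (log2, y axis) of each region shared by all lines, by position on chromosome 21 in Mb (x axis, hg19), for TALL-1 (orange) and the 5 other lines (grey), 1 library each. The 8 parts of the chromosome have TALL-1 medians of 0.73 to 1.36 up to 40752697 and of −0.29 and −0.28 beyond it; the step lies between 43299891 and 43429640.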

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

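The permutation of runs was set before the data were examined, and its bound for the run on chromosome 2 was written after. The tests below of detection limits, of call rates at matched regions and of all 3 explanations for chromosome 21 were chosen after the result was seen; the tests of weak peaks, of the density trend in line-only regions and of lowered coverage were written down first. With 1 library per line, a difference between cell lines is confounded with a difference between libraries, and this biological explanation stays open and untested in each pattern.

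CCRF-CEM had the most line-only regions although its relative tag depth was the lowest. Its median fold enrichment over the local background was the highest, 7.93 against 6.83 to 7.12 in the other lines. Whether this bears on the count was not tested. Weak peaks near the threshold are argued against as the whole cause: with equal numbers of the strongest peaks CCRF-CEM still had 1.54 times as many as the next line. That cut also removes weak peaks of other lines and so makes new line-only regions. TALL-1, which kept all its peaks, rose from 1490 to 2060. The ratio is therefore not a measure of weak CCRF-CEM peaks alone. Detection limits of the other libraries could not be excluded. Scaled by pileup ratios of the same density class, 66.2% of the CCRF-CEM line-only regions would have reached the threshold in all 5 others. With 1 ratio for the genome the share was 83.9%, and both lay above the 60% set as the bound. With the threshold raised by 1 tag the shares were 57.7% and 78.1%, and only the former lay below 60%. The authors' p-value, taken as the chance of more than t tags, calls for the threshold without the added tag. Shares above 60% do not exclude detection limits, because of the bias given below. A coverage trend with region density could not be excluded either: in the densest of 3 classes CCRF-CEM had 1.77 times the mean of the other lines, above the bound of 1.5 set beforehand, but that bound was a poor one, since HBP-ALL had 1243 line-only regions there and CCRF-CEM 1106. The scaled shares are also biased upward, because line-only regions are picked for being high in that line.

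TALL-1 pileups on chromosome 21 were high. The trend with region density is argued against, since the median was 1.08 with the trend removed. A few strong regions are argued against, since 6 of 8 parts of the chromosome had medians whose intervals lay above 0.2; a test written first had left this open, with 76.4% of regions above the TALL-1 median, between its bounds of 75% and 90%. A gain of the whole chromosome is argued against by the last of the 8 parts, at −0.28, where the log2 ratio of TALL-1 to each other line taken singly differed by −1.07 to −2.25 from that over the first 6 parts; a test written first had compared the lower 44 with the upper 45 regions, which differed by 0.088 and so met what a whole gain predicts, because it could not see the drop near the end. In the search for steps 0 of 1000 reordered draws gave a step as large as −1.40, when steps were weighted by the numbers of regions on their sides. No draw as large was found in 88 of 138 combinations of line and chromosome either, so this sets the step little apart. It had the same sign against every other line, but this shows a change of level and not its cause. A gain of part of the chromosome is a candidate explanation and stays open.

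TALL-1 lacked peaks over a stretch of chromosome 2. Chance clustering of independent missed regions is argued against, since 0 of 1000 permuted placements gave a run of 13 and the longest had 12. With recurrent regions of at least 4 other lines, however, the run had 6 regions and did not pass. The permutation kept neither chromosome nor region density. TALL-1 relative pileup was −0.33 over all of chromosome 2, and −0.21 with the density trend removed. The permutation therefore does not separate the stretch from a lower level along the chromosome. Coverage lowered to 50% could not be excluded: 19.3% of the regions in the stretch would pass the threshold at that coverage, between the bounds of 10% and 20% set beforehand. Call rates at regions with as many other lines and a like predicted pileup gave 11.05 expected TALL-1 calls at that coverage. Among the 57 regions 0 calls were observed. Of the expected calls 7.175 fell on the 13 recurrent regions, which were picked for having no calls, so that part excludes nothing. The other regions of the stretch were not picked in this way. They were not tested separately, so no conclusion is drawn from them. The tests treat neighbouring regions as independent, and complete loss of the stretch and a closed domain in TALL-1 were not tested and remain open.

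Among 55 quantities compared over the 6 lines, 2 had a line farther from the rest than Dixon's 95% critical value allows, and chance alone would give about 2.75. The share of intervals on chromosome 17 was 2.56% in CCRF-CEM, with the next line at 4.10%. The median relative pileup on chromosome 18 was −0.60 in MOLT-4. Peaks on the mitochondrial genome, which the comparisons do not use, appeared in every list: 31 summits in CCRF-CEM, 31 in DND-41, 34 in HBP-ALL, 30 in KOPT-K1, 28 in MOLT-4 and 28 in TALL-1.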

How the results depend on the processing

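The local background limit, the removal of CCRF-CEM and HBP-ALL together, the correlation of pileups, the use of all merged regions for runs and all settings for relative pileups were chosen after seeing the data. The count of regions shared by all lines stayed within 1.5 times its value under each setting run, leaving out each line included, and so did the count of regions of 1 line, except that it fell to 10102 without CCRF-CEM and HBP-ALL together, which held 6420 and 4654 of these regions. CCRF-CEM had the most line-only regions in each of 6 settings. DND-41 and KOPT-K1 were the most similar pair under each measure, and the highest and lowest pair values were 0.570 and 0.408 at a −log10 q of at least 5, 0.566 and 0.411 with equal numbers of peaks, 0.472 and 0.321 with summit windows of 250 bp on each side, 0.684 and 0.501 with a reciprocal overlap of 50%, and 0.806 and 0.514 as Spearman correlations. The lowest pair was CCRF-CEM and TALL-1 with equal numbers and by correlation. Runs beyond the permuted level numbered 3 at the stricter q, 7 with equal numbers and 8 with all merged regions, each with the TALL-1 run on chromosome 2 among them; with recurrent regions of at least 4 other lines there was 1, a MOLT-4 run on chromosome 1, and the TALL-1 run had 6 regions and did not pass. With equal numbers the longest were CCRF-CEM runs on chromosome 19, of 17 regions from 11750322 and 13 from 58095253, and the TALL-1 run had 11. CCRF-CEM shares on chromosomes 17 and 19 were 2.24% and 2.20% with equal numbers of peaks. The cause of the shifts in similarity, runs and shares was not tested. Counting every main result under every setting, 27 values lay within the limits set and 16 were counted as moved, those printed here. No limit was set for the pair values, so each of them was counted as moved whatever its size. The correlations are also on another scale than the Jaccard index. The 27 include the count of 1 run with at least 4 other lines, which is not the run found in the main analysis. No paired analysis was possible because each line has 1 library and no test compares groups. The alternatives set out for promoter shares, gene lists, windows around transcription factor genes and motifs were not run, as no annotation or genome of hg19 was used here. CCRF-CEM had the fewest tags on the relative scale, and its 971 regions missing in that line alone include an unknown number below detection.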

Other observations

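The search for steps along chromosomes, the density trend and the runs over all merged regions were chosen after seeing the data. With all merged regions of the other lines counted, TALL-1 had its longest run without a peak on chromosome 4, from 178394942 to 183747903, where 61 regions of the other lines went without a TALL-1 peak. Of these, 30 held a peak in CCRF-CEM, 21 in HBP-ALL, 11 in MOLT-4, 10 in DND-41 and 10 in KOPT-K1. Over all chromosomes TALL-1 lacked a peak at 61.6% of the other lines' regions, and its permuted 95th percentile of the longest run was 44. Within the same place MOLT-4 had a run of 30 regions, from 180908310 to 183747903, which did not exceed its permuted percentile of 35.

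Relative pileup changed level along several chromosomes. After the density trend was removed, the best single split gave a step of over 0.5 in 11 of 138 combinations of line and chromosome, with at least 15 regions on each side. Against each other line taken singly 9 of the 11 kept their sign, and those of HBP-ALL on chromosomes 5 and 21 did not: the latter was −0.28 against MOLT-4, and the former 0.47 against CCRF-CEM. The largest was that of TALL-1 on chromosome 21, −1.40 between 43299891 and 43429640, and −1.11 to −2.38 against the single lines. Of 1000 reordered draws 0 were as large. The −2.38 was against MOLT-4, and the next largest was −2.08, against HBP-ALL. MOLT-4 itself stood at 0.28 on chromosome 21 up to 40818036 and at 1.12 from 42733641 on. This MOLT-4 step was 0.37 to 2.36 against the single lines, with the highest value against TALL-1. A change of level near the end of chromosome 21 was therefore not particular to TALL-1. MOLT-4 stood at −0.90 on chromosome 7 up to 16686337 and at 0.12 from 17979503 on, and this step was 0.82 to 1.39 against each of the other lines taken singly. CCRF-CEM stood at 0.18 on chromosome 5 up to 172572041 and at −0.71 from 173043034 on, a step of −0.54 to −1.72 against the single lines. KOPT-K1 stood at −0.08 on chromosome 20 up to 54934383 and at −0.87 beyond, a step of −0.78 to −1.30 against the single lines. Permuting the order of regions gave no step as large, weighted by the numbers of regions on its sides, in 88 of the 138 combinations. This permutation treats neighbouring regions as independent.

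Relative pileup in CCRF-CEM fell with the number of shared regions nearby (Spearman correlation −0.41 across 9042 regions), and so did those of DND-41 (−0.17) and KOPT-K1 (−0.17). MOLT-4 (0.35), TALL-1 (0.30) and HBP-ALL (0.16) went the other way, as some lines must when each value is relative to the mean of the 6. The first principal component of relative pileup held 45.3% of the variance, with CCRF-CEM at one end and TALL-1 at the other.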
